A study of Mus musculus with 16 samples.

How the data were processed

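RNA was sequenced from 16 whole tumours grown in mice. The tumours were xenografts of AU565(pv), a human breast cancer cell line with amplified HER2, grown in a mammary fat pad. The hosts were SCID mice, which lack mature T and B lymphocytes. Treatment began when tumours measured 20 to 25 mm2, and tumours were harvested on day 2, per the labels' protocols. Each of 4 groups held 4 mice: vehicle, trastuzumab at 10 mg/kg, panobinostat at 15 mg/kg on days 0 and 1, and both drugs together. The labels give the day of trastuzumab as day 0 in the treatment protocol and as day 1 in the series design, so its exposure time is uncertain. Every mouse number occurred once over the 16 libraries, so no library was paired with another, and each library came from its own animal.

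The authors deposited 1 table of raw read counts per mouse gene symbol. Per the submitters' processing notes, base calling used CASAVA 1.8.2, alignment used TopHat2, counting used HTSeq and the genome build was mm10. Settings, the annotation release and any separation of human from mouse reads are not given in the sources used here. The library kit named in the labels does not mark strand, so reads from overlapping genes on opposite strands could not be told apart. Because the tumour cells are human and the counts are for mouse genes, the values are read here as mainly those of the mouse host compartment. The share of human reads among them was not measured. Human reads that aligned to a conserved mouse gene could add to its count.

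The table listed 24681 gene symbols, and none of its lines lacked a gene. For 1327 symbols a dot stood in place of a value in all 8 panobinostat-treated libraries, and no symbol had a dot in some of them only. These symbols were left out, and none would have passed the filter on low counts if read as 0. Every listed symbol had at least 1 count over the 8 vehicle and trastuzumab libraries. A gene seen in panobinostat-treated libraries alone would therefore be missing from the table. The remaining 23354 symbols had a value in all 16 libraries. The total count of a library was the sum of all its given values. Totals of vehicle and trastuzumab libraries therefore include 142 to 2963 counts of the symbols left out.

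Total counts ranged from 4848244 to 8140782 per library. Counts of replicate libraries differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 4.32 to 37.0 within groups. No pair was treated as 1 library.

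The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling and filterByExpr, which left 15610 genes. All 16 libraries entered 1 fit with 1 mean per group, so that the groups shared an estimate of the spread. The common biological coefficient of variation was 0.183. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. The comparisons were each drug against vehicle, the combination against vehicle and against each single drug, and the interaction of the drugs. The effect of each drug averaged over the other was added after the data were examined. Levels are given as TMM-scaled CPM (counts over the scaled total), mean ± SD over 4 libraries, and fold changes as log2 values with an approximate standard error (SE). This SE was the absolute log2 change divided by the square root of the F statistic, and was not estimated by the fit itself.

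Gene lists, the rule for naming genes, the tests and the alternatives other than those named below as added were fixed before the data were examined. The 32 lists covered interferon and antigen presentation genes, cytokines, markers of cell types a tumour or its fat pad could hold, and responses to drugs or stress. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 32 lists within a comparison. Members were also counted with the adjustment over the list alone. A list score was the mean log2 CPM of the list's tested genes in a library, with a prior count of 2, and was compared between groups with exact two-sided permutation tests. With 4 libraries against 4, such a test cannot give a p below 0.0286. Over the 160 tests in this family, that p became 0.190 after adjustment, so no single score difference could pass.

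Genes are named by these rules. For each comparison between groups, the 5 largest increases and the 5 largest decreases were taken among called genes whose groups of 4 libraries did not overlap. A mean of at least 1 CPM in the higher group was required, and predicted loci without an assigned symbol were skipped. Up to 3 called members of smallest adjusted p were taken from each list. Cxcl9, Cxcl10, Cxcl11, Ccl5, Ncr1, Gzmb, Ifng, Tnf, Fcgr4, Cd274, Cdkn1a, H1f0, Erbb2 and Krt8 were always included where tested, and Ifng did not pass the filter. Genes named outside these rules are said to have been chosen after their values were seen. Some genes that meet the rules are not reported here.

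The procedure was tested on simulated counts drawn for the 15610 genes from the real means and library sizes. Each simulation changed 200 genes. For panobinostat against vehicle, edgeR recovered 40.3% of the genes changed by 1.5 times, 59.7% of those changed by 2 times and 92.4% of those changed by 4 times. For the interaction the shares were 2.99%, 35.8% and 87.9%. False calls made up 0.775% of the calls for panobinostat against vehicle, 4.84% for trastuzumab against vehicle, 4.41% for the combination against vehicle, 9.30% for the combination against panobinostat, 3.12% for the combination against trastuzumab and 6.67% for the interaction. In a simulation of the combination against vehicle, DESeq2 gave 12.8% false calls and limma voom 4.44%. The simulated list that was raised was called by both forms of camera, and 0 of 50 unchanged lists were called by either. Simulated genes were drawn independently of each other, so this result says nothing about false list calls among correlated genes.

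Alternatives were relative log expression, upper-quartile and total-count scaling, no filter and a stricter filter of 5 CPM in 4 libraries. Other alternatives were DESeq2 1.42.0, limma voom with quality weights, robust dispersion, a fit of the compared groups alone, a luminal tumour gene score as a covariate, and leaving out each library in turn. An adipocyte gene score as a covariate, and leaving out vehicle replicate 21 from comparisons that do not use it, were added after the data were examined. Gene positions were taken from a GENCODE mouse annotation of the mm10 build by exact symbol, which matched 14608 of the 15610 tested genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.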

Results

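The mouse genes expressed in 16 HER2-positive breast tumour xenografts were measured by RNA sequencing 2 days after the start of treatment. Trastuzumab is an antibody against HER2, and panobinostat is an inhibitor of histone deacetylases. The 4 groups of 4 mice form a design with and without each drug. It addresses what each drug does to the tumour's host compartment, and whether the drugs together do more than either alone. Mean total counts were 5999016 ± 793452 for vehicle, 6036206 ± 1041244 for trastuzumab, 5820239 ± 385315 for panobinostat and 6472968 ± 1281304 for the combination (SD, n = 4 each). The totals differed by less than the spread between libraries. The smallest exact permutation p of the 5 comparisons between groups was 0.457, for the combination against panobinostat. List results are given with an estimated correlation between genes. At a preset correlation of 0.01, camera called 17 of 32 lists for panobinostat against vehicle, but other groupings of the same libraries called a median of 10.

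Panobinostat alone raised the neuronal list and lowered the immediate early and erythroid lists. Vgf, which encodes a secreted neuropeptide precursor, rose from 2.68 ± 1.09 to 21.7 ± 5.42 CPM (SD, n = 4 each), a log2 change of 3.02 (SE 0.36, adjusted p = 0.00159). Smoc2, a matrix-associated calcium-binding protein gene, fell from 61.7 ± 9.76 to 25.3 ± 1.96 CPM, a log2 change of -1.28 (SE 0.15, adjusted p = 0.00159). Of the 15610 genes tested, 30 were called, 22 higher and 8 lower. Vgf lies on chromosome 5 at 137026392 to 137033351 and Smoc2 on chromosome 17 at 14279506 to 14404790 of the mm10 build, and neither shares exons with another annotated gene.

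The other large increases were Fxyd7, a regulator of the sodium pump (log2 change 2.29, adjusted p = 0.0384), Ptprn, a secretory granule protein gene (1.65, adjusted p = 0.0384), Ifit1, an interferon-induced antiviral gene (1.50, adjusted p = 0.0496), and Tesc, a calcium-binding protein gene (1.41, adjusted p = 0.0408). Of 16 neuronal genes tested, 9 were higher with the adjustment over the list alone and 1, Vgf, over all genes. The list median was 0.73, with adjusted p = 0.0152 with an estimated correlation and 0.00674 by fry. Per1, a circadian clock gene that responds to glucocorticoids, rose by 0.56 (adjusted p = 0.0384). Its list did not pass: the median of 13 glucocorticoid response genes was -0.01, with adjusted p = 0.833 with an estimated correlation.

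Of 16 immediate early genes, which growth factors switch on within minutes, 3 were called lower and 7 were lower over the list alone. Fos fell by 0.96 on the log2 scale (adjusted p = 0.0384), Cyr61 fell by 0.86 (adjusted p = 0.0384) and Egr1 fell by 0.59 (adjusted p = 0.0339). The list median was -0.37, with adjusted p = 0.0119 with an estimated correlation and 0.00302 by fry. Pdgfrl, a platelet-derived growth factor receptor-like gene, fell by 1.01 (adjusted p = 0.0408). None of the 6 erythroid genes was called over all genes, but 5 were lower over the list alone. Their median was -1.69, with adjusted p = 0.0152 with an estimated correlation and 0.0362 by fry.

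All 28 type I interferon response genes tested had a positive log2 change, with a median of 0.91. Over all genes 1 was called, Ifit1, and 26 were higher with the adjustment over the list alone. The adjusted p was 0.0598 with an estimated correlation and 0.0505 by fry, so the list did not pass either test. Of 21 genes induced by interferon gamma, 16 were higher over the list alone (median 0.98, adjusted p = 0.0598 with an estimated correlation). The chemokine Cxcl10 stood at 10.2 ± 3.54 CPM in vehicle and 42.3 ± 10.9 CPM in panobinostat tumours, a difference that missed the threshold (adjusted p = 0.0632). The same held for Cxcl11 (adjusted p = 0.122), Cxcl9 (0.260) and the Fc receptor gene Fcgr4 (0.122). Within MHC class II presentation genes, H2-Ob, an antigen-loading modulator, was called (log2 change 0.83, adjusted p = 0.0462).

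All 38 cell cycle genes had a positive log2 change (median 0.40), with 8 higher over the list alone and 0 over all genes, and adjusted p = 0.189 with an estimated correlation. The 17 genes listed as responders to histone deacetylase inhibition had a median of -0.13 (adjusted p = 0.833 with an estimated correlation), and none was called. Cdkn1a, the p21 gene, gave a log2 change of 0.24 (adjusted p = 0.766), and the linker histone gene H1f0 gave -0.22 (adjusted p = 0.697). The macrophage list gave 0.06 (adjusted p = 0.830) and the luminal HER2-type list 0.01 (adjusted p = 0.913), both with an estimated correlation.

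The count of 30 rested on all 8 libraries. It was 16 with the luminal score as a covariate, 46 with total-count scaling, 54 by limma voom, 58 when only these groups were fitted, 154 by DESeq2 and 218 with the adipocyte score as a covariate. It was 3 without vehicle replicate 3, vehicle replicate 21, panobinostat replicate 4 or panobinostat replicate 7, 5 without vehicle replicate 6 or 29, 6 without panobinostat replicate 8 and 12 without panobinostat replicate 13. Vgf and Smoc2 were called in all 8 such fits, with largest adjusted p of 0.0177 and 0.0112, and the other 11 named genes that were called in the full comparison in none.

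**Figure D1:**
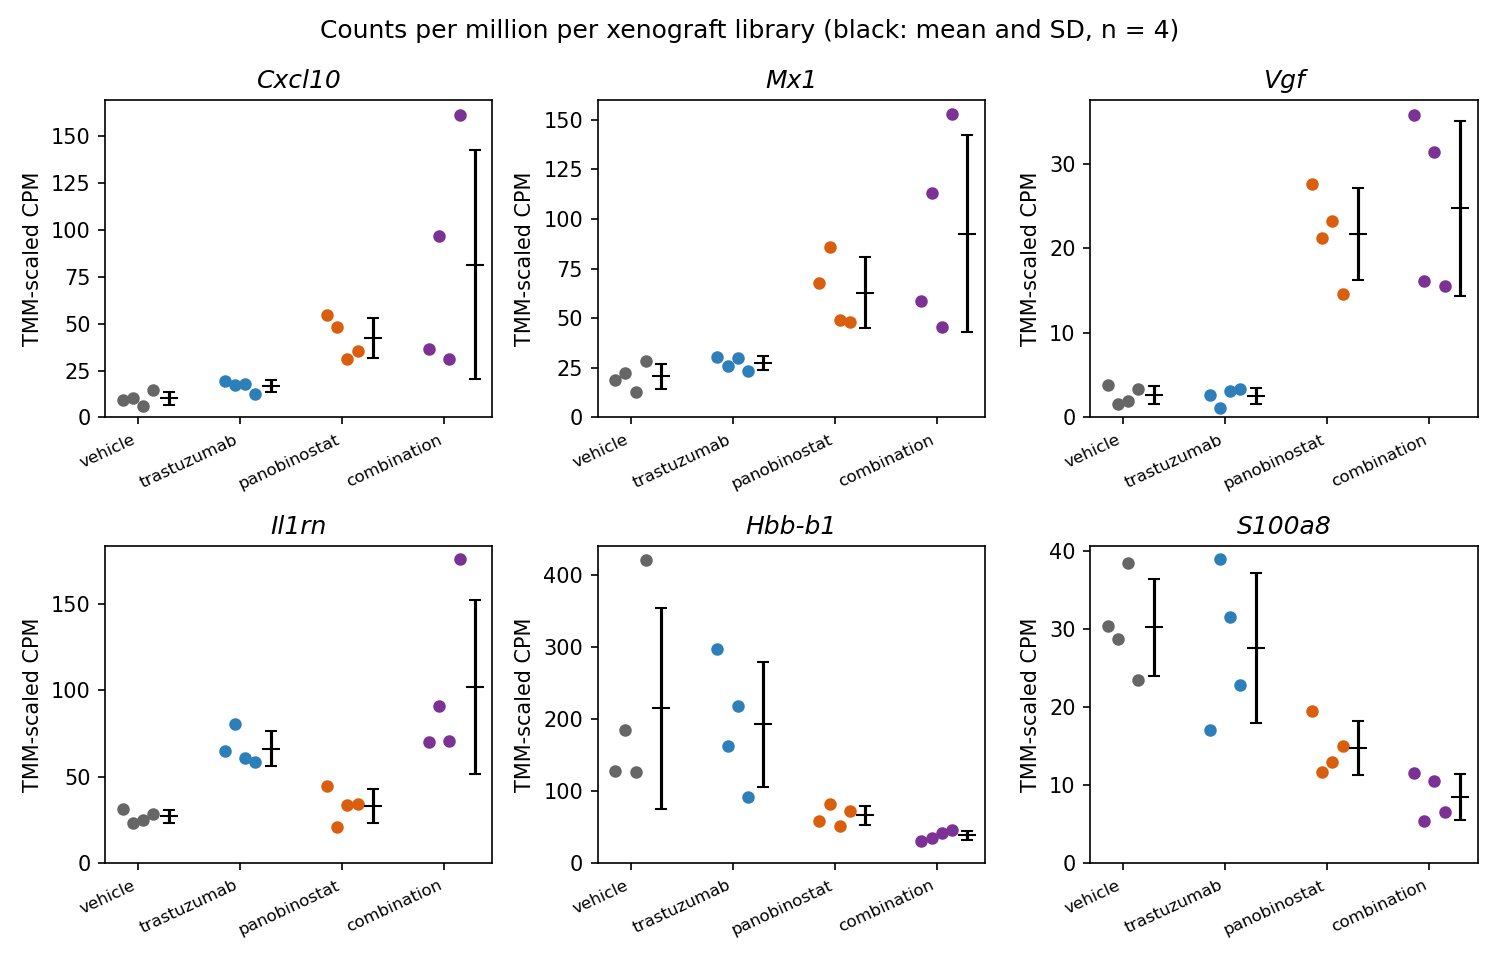
TMM-scaled CPM in each of the 16 libraries by treatment group, with a separate linear axis from 0 for each of 6 genes; the black marks are the mean and SD of 4 libraries. Vgf was 2.68 ± 1.09 CPM in vehicle and 21.7 ± 5.42 CPM in panobinostat tumours, Il1rn was 26.9 ± 3.61 CPM in vehicle and 66.2 ± 10.0 CPM in trastuzumab tumours, and Hbb-b1 was 215 ± 140 CPM in vehicle and 38.2 ± 6.77 CPM in combination tumours.

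Trastuzumab alone gave no gene past the threshold. By edgeR 0 of 15610 genes were called, with 549 at an unadjusted p under 0.05, while DESeq2 called 12 genes and limma voom 0. The always-named genes gave log2 changes of 0.72 for Cxcl10 (SE 0.45), 0.45 for Fcgr4 (SE 0.21), 1.49 for Gzmb, a cytotoxic granule enzyme gene (SE 0.71), 0.82 for Ncr1, a natural killer (NK) cell receptor gene (SE 0.48), and 0.24 for Erbb2 (SE 0.25). None passed, with adjusted p = 1.00 for each of them. Chosen after their values were seen, Il1rn, which encodes an antagonist of the interleukin 1 receptor, gave 1.30 (SE 0.27, adjusted p = 0.398), Clec7a, a fungal glucan receptor gene of phagocytes, gave 0.78 (SE 0.16, adjusted p = 0.398), and H2-Ab1, an MHC class II chain gene, gave 0.52 (SE 0.11, adjusted p = 0.442).

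Of 11 MHC class II presentation genes, 10 had a positive log2 change after trastuzumab and 8 were higher with the adjustment over the list alone. Their median was 0.42, with adjusted p = 0.0762 with an estimated correlation and 0.0770 by fry. All 16 NK cell marker genes were positive (median 0.99), and 0 were higher over the list alone (adjusted p = 0.617 with an estimated correlation). Luminal HER2-type genes had a median of 0.25 (adjusted p = 0.617), type I interferon genes 0.22 (adjusted p = 0.727) and Fc receptor and phagocyte oxidase genes 0.16 (adjusted p = 0.617), all with an estimated correlation. None of the 32 lists passed with an estimated correlation or by fry. In simulated counts of this size for this comparison, edgeR recovered 14.9% of genes changed by 1.5 times and 70.1% of those changed by 2 times.

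Tumours given both drugs differed from vehicle in 343 genes, 265 higher and 78 lower. Among the largest increases were the interferon-induced chemokines Cxcl11 and Cxcl10, together with Vgf, Crtam and Gzmb, and among the largest decreases were the haemoglobin genes. Cxcl10 went from 10.2 ± 3.54 to 81.5 ± 61.0 CPM (a ratio of 8.01, SE of the log2 change 0.44, adjusted p = 0.00162). Cxcl11 went from 2.88 ± 0.975 to 31.1 ± 28.6 CPM (log2 change 3.45, SE 0.56, adjusted p = 0.00356) (SD, n = 4 each). Both sit within the chemokine cluster on chromosome 5. The Cxcl10 exons, at 92346638 to 92348889, overlap Art3 on the opposite strand, and those of Cxcl11, at 92359544 to 92365485, overlap the predicted gene Gm2673. Reads of the 2 strands could not be told apart.

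Of 28 type I interferon response genes, 20 were called higher and 28 were higher over the list alone, with a median of 1.26. On the log2 scale Mx1 rose by 2.16 (adjusted p = 0.00216) and Rsad2 by 2.01 (0.00356), while Ifit1 rose by a ratio of 3.48 (0.00388), all with antiviral functions. The adjusted p was 0.0590 with an estimated correlation and 0.0137 by fry. Of 21 genes induced by interferon gamma, 17 were called higher (median 1.48), among them Gbp5, a guanylate-binding protein gene, at 1.99 (adjusted p = 0.00488). Here the adjusted p was 0.0433 with an estimated correlation and 0.0122 by fry. Nlrc5, the transactivator of MHC class I genes, rose by 1.41 (adjusted p = 0.00546), and 2 of 18 class I presentation genes were called (median 0.42, adjusted p = 0.315 with an estimated correlation).

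Antigen presentation through MHC class II moved as a list: 8 of 11 genes were called higher (median 0.59, adjusted p = 0.0433 with an estimated correlation and 0.00246 by fry). H2-Ob rose by 1.21 (adjusted p = 0.00108), Ciita, the master regulator of class II genes, by 1.04 (0.00488) and H2-DMb1, a peptide exchange factor gene, by 0.67 (0.00689). Of the 24 chemokines, 6 were called, including the monocyte attractant Ccl12 (1.19, adjusted p = 0.00635), and the list gave adjusted p = 0.116 with an estimated correlation. The Fc receptor genes Fcgr1 (1.03, adjusted p = 0.00129) and Fcgr4 (1.41, 0.00184) were called. So were 2 dendritic cell markers, the integrin Itgax (1.07, 0.00568) and the costimulator Cd86 (0.96, 0.00357). The score of the dendritic cell list differed by 0.15 (exact permutation p = 0.314). Il1rn rose by 1.92 (adjusted p = 0.00129). The macrophage list gave a median of 0.12 (2 of 21 called, adjusted p = 0.438 with an estimated correlation), and the Fc receptor and phagocyte oxidase list 0.25 (3 of 19 called, adjusted p = 0.201).

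Among NK cell markers, 3 of 16 were called: the receptor Klrk1 (1.97, adjusted p = 0.00488), the chemokine Xcl1 (1.87, 0.0109) and Gzmb (2.65, 0.0430). All 16 had a positive log2 change (median 1.07), with adjusted p = 0.199 with an estimated correlation and 0.0638 by fry. Crtam, a receptor of cytotoxic lymphocytes, rose by 2.66 (adjusted p = 0.00730). Ncr1 gave 0.98 (adjusted p = 0.376) and Ccl5 1.02 (adjusted p = 0.422), and neither passed, nor did Tnf (0.66, adjusted p = 0.337). The immune checkpoint ligand gene Cd274 rose by 1.41 (adjusted p = 0.0382). The calls of Gzmb and Cd274 were lost without vehicle replicate 3, 6, 21 or 29 or combination replicate 11 or 22, with adjusted p up to 0.179 for Gzmb and 0.129 for Cd274.

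The erythroid genes were the largest decrease: 5 of 6 were called lower, with a median of -2.44 and adjusted p = 0.0108 with an estimated correlation. Hbb-b1 fell from 215 ± 140 to 38.2 ± 6.77 CPM (log2 change -2.49, SE 0.38, adjusted p = 0.00216), and Hbb-b2 fell by 2.67 (adjusted p = 0.00149). Hba-a2 fell by 2.57 (0.00358) and Hba-a1 by 2.40 (0.00568). Alas2, which encodes the erythroid enzyme of haem synthesis, fell by 2.07 (0.0325), a call lost without vehicle replicate 3 or 29 or combination replicate 2, 11 or 22 (adjusted p up to 0.128). The alpha and beta globin genes exist as near-identical copies whose reads counting can divide, so the single values of each copy are uncertain.

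Neutrophil markers went both ways. S100a8 and S100a9, which encode the subunits of calprotectin, fell by 1.85 (adjusted p = 0.00184) and 1.96 (0.00488), while the formyl peptide receptor gene Fpr2 rose by 1.56 (0.00964). In all 3 were called lower and 1 higher of 12 (median -0.59, adjusted p = 0.201 with an estimated correlation). Vgf rose by 3.20 (adjusted p = 0.000434) and Unc13a, which primes synaptic vesicles, by 1.14 (0.00743), with 3 of 16 neuronal genes called (adjusted p = 0.0803 with an estimated correlation). Cyr61 fell by 1.03 (adjusted p = 0.00216) and the matrix protein gene Sparc by 0.62 (0.0139), a call lost without vehicle replicate 6 or combination replicate 11 (adjusted p up to 0.0580). The mouse HER2 gene Erbb2 gave 0.06 (adjusted p = 0.952) and the mouse keratin gene Krt8 -0.19 (0.668), and neither was called. Human reads may add to both counts. Their share was not measured, so neither value can be assigned to the mouse gene alone or to the tumour's own human gene.

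The 343 calls became 201 without combination replicate 11 and 210 without vehicle replicate 6, 91 with the luminal tumour gene score as a covariate, 735 with the adipocyte score, 127 when only these groups were fitted and 537 by DESeq2. Of the 48 named genes that were called, 32 stayed past the threshold without each library in turn.

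**Figure D2:**
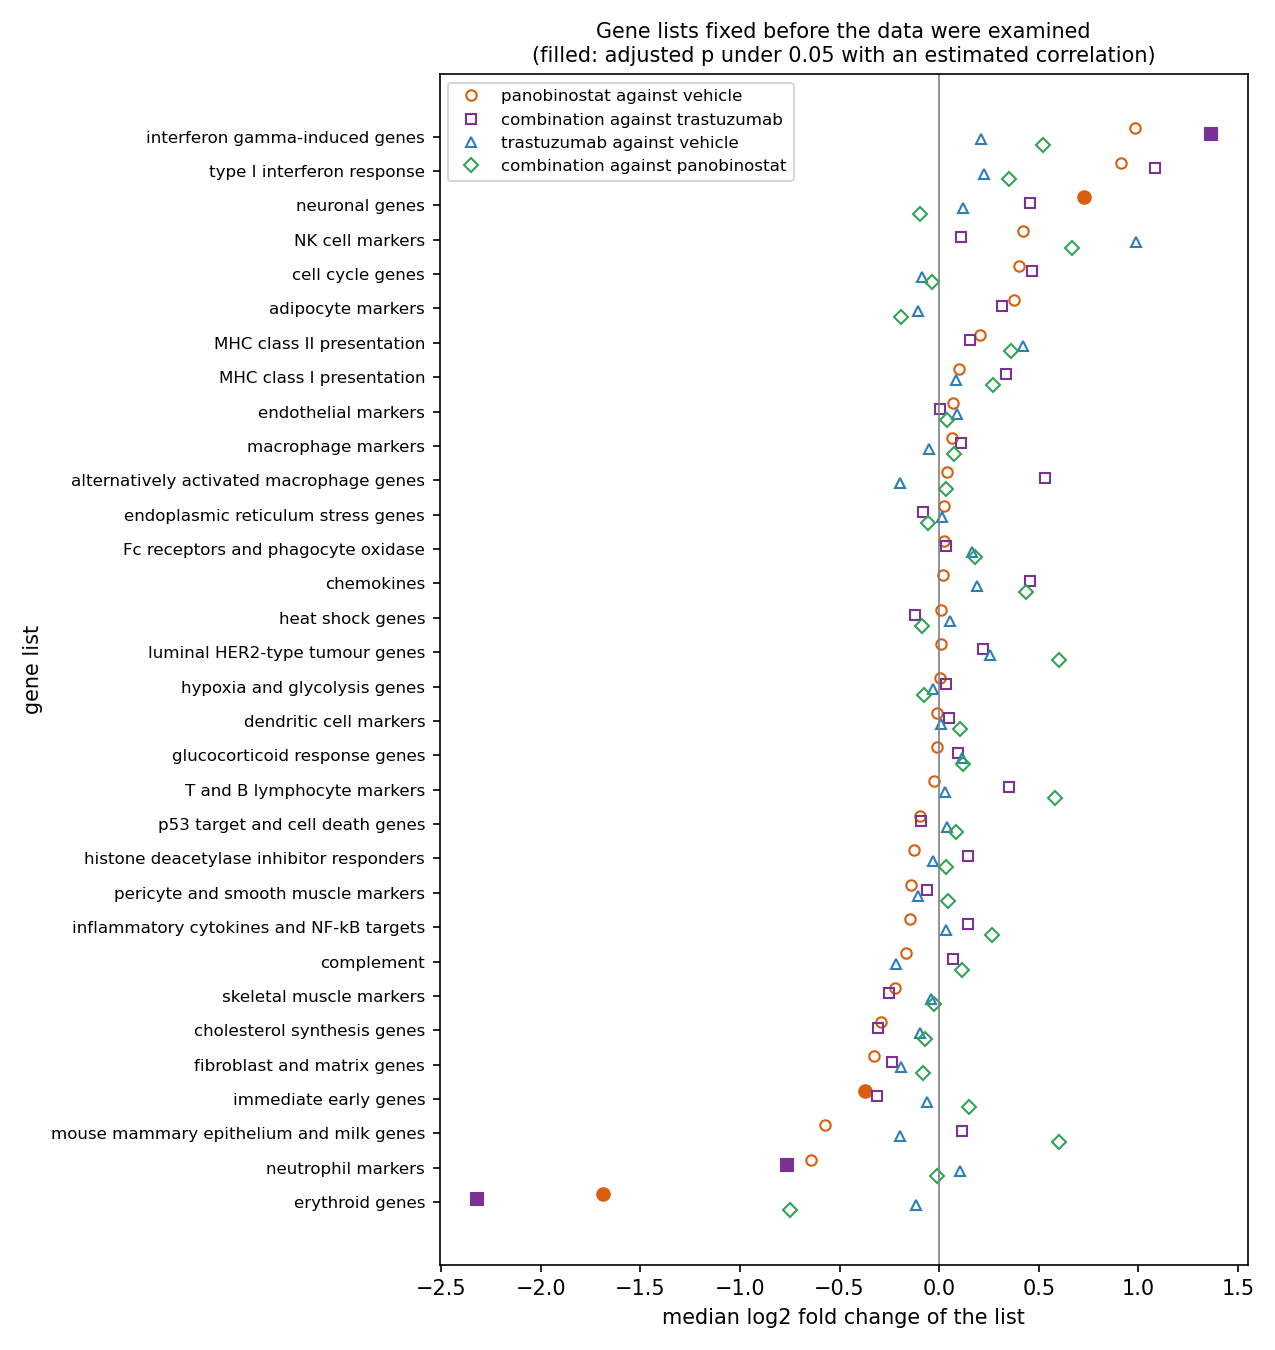
Median log2 fold change (horizontal axis) of each of 32 gene lists (vertical axis) in 4 comparisons; a filled symbol marks an adjusted p under 0.05 with an estimated correlation. The erythroid list lies at -1.69 for panobinostat against vehicle and -2.32 for the combination against trastuzumab, and the interferon gamma-induced list at 0.98 and 1.36.

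Adding panobinostat to trastuzumab raised genes induced by interferon gamma and lowered erythroid genes and neutrophil markers, with 98 genes called, 73 higher and 25 lower. Vgf again led, from 2.54 ± 1.00 to 24.7 ± 10.4 CPM (SD, n = 4 each; log2 change 3.28, SE 0.36, adjusted p = 0.000973), and was called without each of the 8 libraries in turn. Of 21 genes induced by interferon gamma, 11 were called (median 1.36, adjusted p = 0.0480 with an estimated correlation), with Cxcl10 at 2.29 (adjusted p = 0.0289), Gbp2 at 1.36 (0.0344) and the immunity GTPase Irgm1 at 1.26 (0.0344). Of 28 type I interferon genes 10 were called (median 1.09), including Mx1 (1.76, adjusted p = 0.0289) and Stat2 (1.11, 0.0344), with adjusted p = 0.0581 with an estimated correlation and 0.0455 by fry. Ccl17, a chemokine of alternatively activated macrophages, rose by 2.25 (adjusted p = 0.0287) and Fxyd7 by 2.10 (0.0287).

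Of 6 erythroid genes, 4 were called lower (median -2.32, adjusted p = 0.00350 with an estimated correlation), and Hbb-b2 fell by 2.52 (adjusted p = 0.0181). Of 12 neutrophil markers, 4 were called lower (median -0.77, adjusted p = 0.0480 with an estimated correlation). S100a8 fell by 1.71 (adjusted p = 0.0235), Retnlg, a resistin-like gene, by 2.31 (0.0427), and Cxcr2, the receptor for neutrophil-attracting chemokines, by 0.84 (0.0348). All 38 cell cycle genes had a positive change, 17 over the list alone (median 0.47, adjusted p = 0.106 with an estimated correlation). Gzmb (1.15, adjusted p = 0.551), Ncr1 (0.16, 0.956) and Cd274 (1.15, 0.158) did not pass. The 98 calls depended on single libraries. They became 4, 3 and 12 without trastuzumab replicate 15, 20 and 24, 8 and 7 without combination replicate 11 and 22, 179 without combination replicate 16 and 49 without vehicle replicate 21, while fitting these groups alone left 5, the luminal score as a covariate left 10, the adipocyte score gave 186, and DESeq2 called 228 and limma voom 155.

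Each of the named genes above other than Vgf lost its call without at least 1 library; for the Cxcl10, Mx1, Gbp2, Irgm1, Stat2 and Ccl17 calls these were trastuzumab replicate 15, 20 or 24 and combination replicate 11 or 22, with adjusted p for Cxcl10 up to 0.118. The Hbb-b2 call was lost without trastuzumab replicate 20 or combination replicate 11 (up to 0.0643), that of S100a8 without trastuzumab replicate 15 or 20 or combination replicate 11 or 22 (up to 0.0766), and that of Fxyd7 without trastuzumab replicate 15, 20 or 24 or combination replicate 22 (up to 0.112). Those of Cxcr2 and Retnlg were lost without any trastuzumab library or without combination replicate 2 or 11, and Retnlg also without 22 (up to 0.128 and 0.161).

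Adding trastuzumab to panobinostat gave no gene past the threshold. By edgeR 0 genes were called, with 700 at an unadjusted p under 0.05, while DESeq2 called 15 and limma voom 0. Tnf gave a log2 change of 1.22 (SE 0.31, adjusted p = 0.650), Gzmb 1.20 (SE 0.56, adjusted p = 0.976), Cxcl10 0.95 (SE 0.39, adjusted p = 0.976) and Ncr1 0.84 (SE 0.47, adjusted p = 0.976). Chosen after their values were seen, Il1rn gave 1.63 (SE 0.27, adjusted p = 0.182), Clec7a 0.90 (SE 0.16, adjusted p = 0.190), Nfkbiz 0.70 (SE 0.13, adjusted p = 0.190) and Ccl4 1.39 (SE 0.31, adjusted p = 0.487). Of 11 MHC class II genes, 7 were higher over the list alone (median 0.36, adjusted p = 0.0938 with an estimated correlation). Of 19 inflammatory cytokines and NF-kB targets, 3 were (median 0.26, adjusted p = 0.0938). No list passed with an estimated correlation.

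The interaction asks whether the effect of panobinostat differed with trastuzumab present. No gene was called by edgeR, with 279 at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. The interaction was 0.97 for Tnf (SE 0.44, adjusted p = 1.00), 0.24 for Cxcl10 (SE 0.60), 0.16 for Cxcl11 (SE 0.80), -0.29 for Gzmb (SE 0.89) and 0.59 for Cd274 (SE 0.48). The standard errors leave room for a 2-fold departure from additivity in each of these genes. In simulated counts the interaction test recovered 35.8% of genes with such a change. A call in the combination that is missing from a single drug is therefore not shown to be an effect of the pair.

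In libraries with no overlap, the effect of panobinostat on mice given vehicle and on mice given trastuzumab was alike across genes (Pearson r = 0.476, Spearman rho = 0.342 over 15610 genes, which are not independent replicates). Of the genes called, 16 were higher and 4 lower in both comparisons, where independent lists would share 0.103 and 0.0128. They included Vgf, Fxyd7, Tesc, Ifit1, H2-Ob and Per1 among those higher, and Smoc2 and Cyr61 among those lower. Both comparisons came from 1 fit and used the same estimate of each gene's spread. Their calls are therefore not independent, and the expected numbers can be too low. This overlap depends on single libraries: panobinostat against vehicle called 3 to 12 genes without any 1 of its libraries, and of these 8 genes only Vgf and Smoc2 were then still called. For the effect of trastuzumab without and with panobinostat r was 0.198 and rho 0.139, a difference that was not tested, and this r ranged from 0.0562 without trastuzumab replicate 15 to 0.316 without trastuzumab replicate 20. It also fell by over 1.5 times without vehicle replicate 3 (0.0695), vehicle replicate 29 (0.106), trastuzumab replicate 12 (0.0711), panobinostat replicate 7 (0.122), combination replicate 11 (0.0886) and combination replicate 16 (0.0647).

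Averaged over trastuzumab, a contrast added after the data were examined, panobinostat changed 471 genes, 324 higher and 147 lower. Here 23 of 28 type I interferon genes were called higher (median 0.98, adjusted p = 0.0227 with an estimated correlation), as were 17 of 21 genes induced by interferon gamma (1.17, 0.0188), 7 of 16 neuronal genes (0.56, 0.0163) and 10 of 38 cell cycle genes (0.42, 0.0746). Lower were 5 of 6 erythroid genes (-2.00, 0.00357), 7 of 16 immediate early genes (-0.35, 0.00915) and 6 of 12 neutrophil markers (-0.73, 0.0244), while 1 other neutrophil marker was called higher. The count stayed between 329 and 480 without each library in turn, and was 946 with the adipocyte score as a covariate. A mixed regrouping of the libraries, with 6 panobinostat-treated ones on 1 side, called 384, and the cause of this was not found.

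Averaged over panobinostat, likewise added, trastuzumab changed 23 genes, all higher. Chosen after their values were seen, they included Il1rn (log2 change 1.46, SE 0.19, adjusted p = 0.00718), Clec7a (0.84, SE 0.11, adjusted p = 0.00718), Itgax (0.76, 0.0243) and the class II genes H2-Ab1 (0.50, 0.0216), H2-DMb1 (0.46, 0.0437) and H2-Eb1 (0.49, 0.0450). H2-Ab1 stood at 630 ± 25.3, 903 ± 125, 675 ± 59.2 and 937 ± 78.9 CPM in vehicle, trastuzumab, panobinostat and combination tumours. Of 11 class II genes 3 were called and 10 were higher over the list alone (median 0.37, adjusted p = 0.0153 with an estimated correlation). Of 16 NK cell markers, 12 were higher over the list alone and 0 over all genes (median 0.82, adjusted p = 0.149 with an estimated correlation). The count became 2 without vehicle replicate 6, trastuzumab replicate 24 or panobinostat replicate 7 or 13, 8 without trastuzumab replicate 12, 9 without vehicle replicate 21, 10 without combination replicate 2, 12 without vehicle replicate 29 or combination replicate 22, and 4 with the luminal score as a covariate, 45 with the adipocyte score and 64 by DESeq2.

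Libraries differed in transcripts of fat and skin genes. The adipocyte list score ranged from 5.61 to 8.35 over all libraries, with an SD within groups of 0.857 for vehicle, 1.05 for trastuzumab, 1.20 for panobinostat and 0.740 for the combination. Group means differed by -0.35 to 0.47 over the 5 comparisons (exact permutation p from 0.514 to 0.971). This is within the spread of libraries, and no such test could pass after adjustment. Vehicle replicate 21 held transcripts of skin epidermis, with 829 counts of Krt1 and 447 of Lor, where no other library had more than 2 of either. The luminal HER2-type score was 4.77 ± 0.348 in combination and 4.29 ± 0.298 in vehicle tumours (SD, n = 4 each, exact permutation p = 0.0857).

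**Figure D3:**
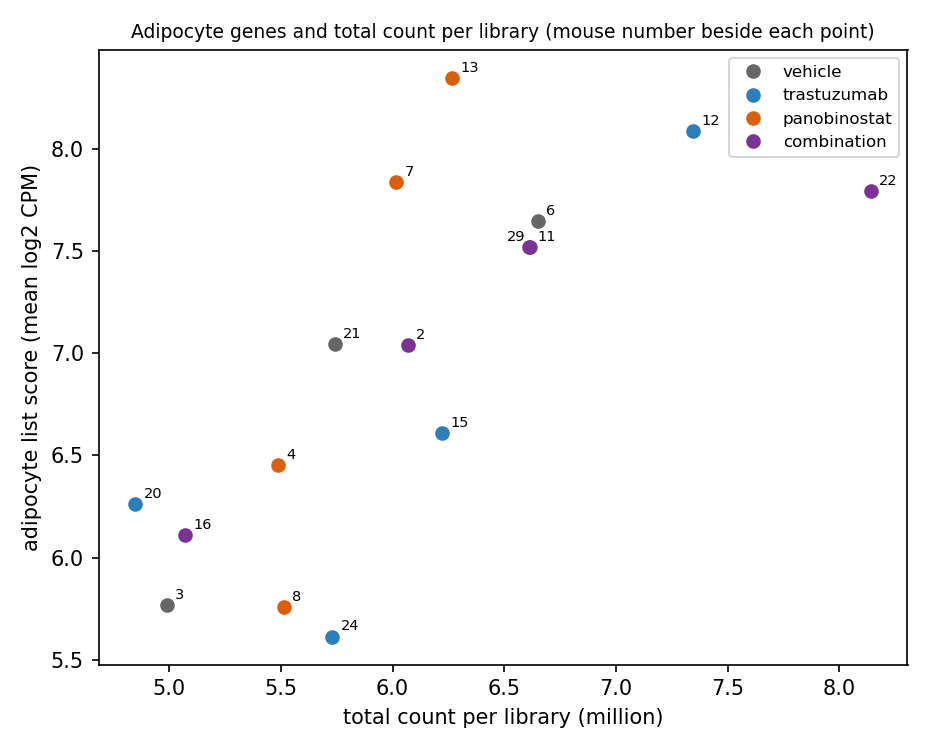
Adipocyte list score (mean log2 CPM, vertical axis) against total count (horizontal axis) for the 16 libraries, coloured by group, with the mouse number beside each point (vehicle 29 lies under combination 11). The score spans 5.61 to 8.35, and its group-centred correlation with the total count was r = 0.782.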

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

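The adipose content test, the regroupings for panobinostat against vehicle, the contrasts averaged over the other drug and the spread required of the test on human tumour RNA were chosen after the result was seen.

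Interferon genes were higher in the 8 panobinostat-treated tumours, with the type I score up by 0.98 (exact permutation p = 4.1e-04, n = 8 each). The exact tests of 8 against 8 libraries permuted separately within mice with and without trastuzumab. Their smallest possible p is 4.1e-04, so results at that p cannot be ranked by it. With the adipocyte score as a covariate, the list median averaged over trastuzumab went from 0.98 to 0.91, so 92.9% was left and adipose content is not the whole cause. More macrophages would raise both scores alike, but the interferon score rose by 0.82 more than the macrophage score (exact permutation p = 4.1e-04), which itself changed by 0.16 (p = 0.0751). A response to panobinostat within host cells remains a candidate explanation, and no test here separates it from a change in other cell types.

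Haemoglobin genes were lower in the panobinostat-treated tumours. Reads shared between the 4 globin copies cannot be the whole cause, since their summed CPM differed by -1.87 on the log2 scale (exact permutation p = 4.1e-04, n = 8 each), where the median single copy differed by -1.84. Alas2, a separate gene, differed by -1.73 (exact permutation p = 4.1e-04). Less blood in the tumours could also lower neutrophil genes: that score differed by -0.42 (exact permutation p = 0.00204), or 26.8% of the difference of -1.58 in the erythroid score. This score averages markers that went both ways. In the combination against vehicle S100a8 and S100a9 fell and Fpr2 rose, so the size of the averaged fall does not measure blood content. Blood content therefore stays open, as does a loss of young red cells.

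Adipocyte genes varied between libraries of the same group. The group-centred score rose with the total count (r = 0.782, permutation p = 3.2e-04, adjusted p = 6.4e-04 over 2 relations, rho = 0.826, n = 16), and r was 0.752 without the 2 farthest libraries. The score is scaled to the total count, so depth alone should not raise it. It spanned 5.61 to 8.35 on the log2 scale, while totals spanned 4848244 to 8140782. The relation met the bounds set for depth before the data were examined. The wider span of the score was not part of that prediction, and it argues against depth as the whole cause. Fat in a sample also adds mouse RNA and so mouse-gene counts, and whether fat raised the totals was not tested. A varying share of human tumour RNA predicted a negative r with the luminal score. The r was 0.412 (permutation p = 0.110, rho = 0.312), which met the bound of 0 set against that explanation but not beyond its spread, so it stays open. The luminal score counts mouse symbols and was not shown to follow human RNA. In vehicle replicate 21, which held epidermal transcripts, it was 4.74, against 4.16 in the next highest vehicle library. The design gives no biological explanation for variation within a group, and none was tested.

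Regrouping the libraries asked how many genes the test calls under other groupings. For a pair of groups all 35 divisions were tried, and otherwise the real grouping and random ones, 100 in all. For the interaction the random ones shuffled all 16 libraries, so the effect of a single drug can enter their contrast and raise their calls. The other groupings mix libraries of different treatments, so a real effect adds to their spread and can lower their calls. Their counts therefore do not show how many genes would be called without any effect. For panobinostat against vehicle 1 of 35 groupings, the real one, called as many as 30 genes, and the highest other called 0. The same held for the combination against vehicle (1 of 35, highest other 1) and against trastuzumab (1 of 35, highest other 3). For trastuzumab against vehicle, the combination against panobinostat and the interaction, which called 0, every grouping (35 of 35, 35 of 35 and 100 of 100) must call as many, so the test says nothing about them. The highest others were 2, 1 and 330, the last in a mixed grouping, which points to structure among the libraries whose cause was not found. For the averaged effects it was 1 of 100 each, with highest others of 384 for panobinostat and 1 for trastuzumab. The 384 came from a grouping with 6 treated libraries on 1 side. Groupings with 7 on 1 side called 7, 47, 3 and 0. The treated share therefore does not account for the 384, and its cause was not found.

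Of 428 sets of 4 libraries, 19 had a library far from the other 3, about the 5% that chance gives. The gap over the whole range is given for each. Among list scores these were NK cell markers in panobinostat replicate 13 (0.880), lymphocyte markers in the same library (0.830), Fc receptors and phagocyte oxidase in combination replicate 22 (0.874), luminal tumour genes in vehicle replicate 21 (0.957) and skeletal muscle markers in trastuzumab replicate 12 (0.859). Among genes they were Cdkn1a (0.840), H1f0 (0.999) and Xcl1 (0.930) in trastuzumab replicate 12, Tesc (0.883), Fpr2 (0.845) and Hmgcs1 (0.834) in trastuzumab replicate 15, and Gzmb in trastuzumab replicate 20 (0.843). The rest were Cxcl9 in vehicle replicate 21 (0.854), Cd86 in vehicle replicate 3 (0.831), S100a9 in vehicle replicate 29 (0.865), H2-Ob (0.901) and Pdgfrl (0.910) in combination replicate 2, Nlrc5 in panobinostat replicate 8 (0.871) and Xcl1 in panobinostat replicate 7 (0.920).

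The effect of panobinostat on 8 lists differed with trastuzumab present when camera assumed a correlation of 0.01. The adjusted p were 0.00963 for MHC class I presentation, 0.00227 for chemokines, 0.00299 for inflammatory cytokines, 9.1e-04 for complement, 0.0146 for fibroblast and matrix genes, 9.9e-04 for mammary epithelium, 0.00299 for erythroid genes and 0.00299 for heat shock genes. None passed with an estimated correlation, where the smallest adjusted p was 0.690. Of 100 groupings 71 called as many lists, but these shuffled all 16 libraries, so the effect of a single drug could enter their contrast. That share therefore does not show how many lists would be called without an interaction.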

How the results depend on the processing

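The adipocyte covariate, the averaged contrasts and the omission of vehicle replicate 21 were chosen after the result was seen. For the counts below the cause of each change was not tested. Relative log expression, upper-quartile scaling, the robust fit and both filters kept every count within 1.5 times. Total-count scaling called 46 genes for panobinostat against vehicle, against 30. No scaling moved the share of higher calls by over 10 points. DESeq2 called 154 for panobinostat, 12 for trastuzumab and 537 for the combination (against 343) over vehicle, 228 (against 98) over trastuzumab, 15 over panobinostat, and 64 (against 23) for averaged trastuzumab. Limma voom called 54 for panobinostat against vehicle and 155 for the combination against trastuzumab. Fitting the compared groups alone gave 58, 1, 127 and 5 for panobinostat, trastuzumab and the combination against vehicle and the combination against trastuzumab. The luminal covariate gave 16, 91 and 10 for panobinostat and the combination against vehicle and the combination against trastuzumab, and 4 for averaged trastuzumab. The adipocyte covariate gave 218, 735 and 186 for the same comparisons, and 946 (against 471) and 45 for the averages. Omitting vehicle replicate 21 left 49 for the combination against trastuzumab. The correlation of panobinostat effects was 0.546 with the stricter filter, against 0.476.

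Leaving out 1 library gave 3 to 12 genes for panobinostat and 201 to 379 for the combination against vehicle, 3 to 179 for the combination against trastuzumab, 329 to 480 for averaged panobinostat and 2 to 33 for averaged trastuzumab. The other comparisons stayed at 0. The correlation of panobinostat effects ran from 0.334 to 0.504, and that of trastuzumab effects from 0.0562 to 0.316. No paired analysis was possible because the groups share no mouse numbers.

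Directions turned for gene values that had not been called and for 2 lists; for the type I interferon list camera changed direction while the median stayed above 0. With limma voom, Ncr1 was -0.0497 in panobinostat against vehicle and Erbb2 -0.00345 in the combination against vehicle, and the interaction was 0.14 for Ccl5, -0.34 for Cxcl10, -0.70 for Cxcl11, -0.15 for Cxcl9 and -0.0934 for Fcgr4. With the luminal covariate, Ccl5 was -0.00703 and Ncr1 -0.0720 in the combination against trastuzumab, and the Ncr1 interaction -0.10. With the adipocyte covariate, Ncr1 was -0.0446 in panobinostat against vehicle and -0.0341 in the combination against trastuzumab, the interaction -0.00132 for Cxcl10 and -0.0460 for Cxcl11, and the adipocyte list median 0.0365 in trastuzumab against vehicle.

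Without 1 library, panobinostat against vehicle ran from -0.0792 to 0.53 for Ccl5, -0.00958 to 0.34 for Erbb2, -0.12 to 0.00981 for Krt8 and -0.41 to 0.35 for Ncr1. Trastuzumab against vehicle ran from -0.0521 to 1.02 for Ccl5, and the combination against vehicle from -0.15 to 0.28 for Erbb2. The combination against panobinostat ran from -0.00961 to 0.28 for Cdkn1a, -0.32 to 0.0939 for Erbb2, -0.16 to 0.0187 for H1f0, -0.21 to 0.0146 for Krt8, and 0.0190 to 0.55 for the type I interferon median. The combination against trastuzumab ran from -0.28 to 1.08 for Ccl5, -0.0470 to 0.23 for Cdkn1a, -0.38 to 0.0398 for Erbb2 and -0.19 to 0.75 for Ncr1. The interaction ran from -0.57 to 0.79 for Ccl5, -0.29 to 0.00721 for Cdkn1a, -0.33 to 0.54 for Cxcl10, -0.61 to 0.49 for Cxcl11, -0.0490 to 0.81 for Cxcl9, -0.22 to 0.28 for Fcgr4, -0.97 to 0.0575 for Gzmb, -0.0213 to 0.17 for H1f0 and -0.31 to 0.63 for Ncr1.

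Of 85 calls of named genes, 85 were kept by DESeq2, 76 by limma voom and 39 with the luminal covariate, and 41 of 83 when only the compared groups were fitted. Of 113 list calls at the preset correlation, 16 were kept with an estimated correlation.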

Other observations

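The contrasts averaged over the other drug and the genes of this part were chosen after the result was seen.

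Single genes among the 23 called for trastuzumab averaged over panobinostat are given here, without a test of any group they form. Clec7a stood at 104 ± 16.2, 178 ± 15.0, 132 ± 30.8 and 246 ± 36.5 CPM in vehicle, trastuzumab, panobinostat and combination tumours (SD, n = 4 each). Slamf8, a receptor that restrains the oxidase of macrophages, rose by 0.98 (adjusted p = 0.0216 by edgeR), the survival gene Bcl2a1d by 0.89 (adjusted p = 0.0216), the B cell and myeloid coreceptor Cd72 by 0.66 (adjusted p = 0.0260) and the surface antigen Cd52 by 0.62 (adjusted p = 0.0216). The count of 23 dropped to 2 without vehicle replicate 6, trastuzumab replicate 24 or panobinostat replicate 7 or 13.

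Ch25h, which makes the antiviral sterol 25-hydroxycholesterol, rose by 1.39 with panobinostat against vehicle (adjusted p = 0.0384 by edgeR) and by 1.96 with panobinostat added to trastuzumab (adjusted p = 0.00344), which share no library. It stood at 8.77 ± 2.33, 12.7 ± 2.53, 23.3 ± 6.22 and 49.1 ± 17.8 CPM in the 4 groups. The early lymphocyte activation gene Cd69 rose by 2.42 in the combination against vehicle (adjusted p = 7.3e-04 by edgeR).

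Vehicle replicate 21 held 829 counts of Krt1, 368 of Krt2, 954 of Krt10, 447 of Lor and 201 of Flg, genes of the cornified epidermis. The highest counts in any other library with a value were 2, 0, 38, 2 and 0. Genes with a dot in the panobinostat-treated libraries held 2963 counts in this library and 142 to 286 in each of the other 7 libraries with values.

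Of 28 fibroblast and matrix genes, 4 were called lower with panobinostat averaged over trastuzumab and 13 were lower over the list alone (median -0.31, adjusted p = 0.260 with an estimated correlation). Of 19 cholesterol synthesis genes, 1 was called lower and 6 over the list alone (median -0.24, adjusted p = 0.193 with an estimated correlation).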
